A study of Mus musculus with 6 samples.

How the data were processed

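The deposited table held counts of reads per gene for 6 libraries, as whole numbers that the authors had not normalised. Per the submitters' processing notes, STAR, featureCounts and DESeq2 were used with the mm10 mouse genome. The versions and the role of each tool are not given in the sources used here, nor is the strand setting of the counting or the treatment of reads that map to several places. Per the labels' protocols the libraries came from a stranded mRNA kit. Without a stated strand setting, overlapping and antisense genes are uncertain, as are close paralogs. Among deposited counts from 1 to 199, 82.0 and 76.6% were even numbers in the CTVhigh libraries and 66.3 to 69.2% in the other 4, where single counting would give about as many even as odd numbers. The table did not say whether both mates of a pair were counted. The 37 mitochondrially encoded genes were at 0 in all libraries.

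The table listed 55573 Ensembl gene identifiers, of which 25979 had no count in any library. Its symbol column had the digit 0 replaced by NA in 9234 of 13601 symbols, so symbols and coordinates were taken by identifier from the GENCODE annotation of mm10, which matched 55394 identifiers and left 179 without a match. Library totals ran from 97865113 to 166059066 counts. Intervals of shares of counts are 95% Clopper-Pearson intervals and cover counting error only, since reads are not independent molecules.

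Samples were grouped by genotype and dye gate from the labels. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts, with all 6 libraries in 1 fit of 3 groups, TMM scaling, edgeR's default filter on low counts and Benjamini-Hochberg adjustment. Genes passed at an adjusted p under 0.05, and 19000 genes were tested. All groups shared 1 estimate of the spread, with 3 residual and 5.53 prior degrees of freedom and a common dispersion of 0.0239. CTVhigh PAX5-ELN was compared with CTVlow PAX5-ELN, CTVlow PAX5-ELN with CTVlow wild type and, as a secondary comparison, CTVhigh PAX5-ELN with CTVlow wild type. Overlaps between comparisons that share libraries were set beside 20 simulations without group effects.

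Before the data were examined, 24 gene lists were fixed, and each was tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg adjustment over the 24 lists). The lists were mitosis, DNA replication, quiescence and cell cycle restraint, MYC and ribosome biogenesis, glycolysis, oxidative phosphorylation, B cell identity and PAX5-activated genes, genes repressed by PAX5, pro-B and large pre-B, small pre-B and later maturation, and stem and multipotent progenitor genes. The others were IL-7 and JAK-STAT response, pre-B cell receptor signalling, interferon, p53 and DNA damage, NF-kB, adhesion and homing, immediate early and handling stress genes, and T cell, NK, myeloid, stromal, erythroid and megakaryocyte, and plasma cell markers. Some genes were placed in several lists, so list results are not separate findings. B cell identity shares Cd22, Cr2, Spib, Bach2, Ikzf3 and Fcer2a with maturation. It shares Cd19, Cd79a, Cd79b and Blnk with pre-B cell receptor signalling.

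Genes were named by a rule fixed at the same time. Immunoglobulin and T cell receptor segments, predicted gene models, pseudogenes, histone genes and sex-linked genes were left out, and a gene needed a passed test, a group mean of at least 5 CPM and no overlap between the libraries of the groups compared. The rule took the 10 largest changes per direction in the first and second comparison, the 5 largest in the third and the 5 largest per direction against both CTVlow groups. It added up to 4 members of each list with the smallest p, or the 2 most abundant members of a list with fewer than 2 that passed. Pax5, Eln, Mki67, Cdkn1b, Ighm, Cd19, Il7r, Kit, Flt3, Myc and Lck were always included, though most are given below for some of the comparisons only.

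The test was checked on simulated counts drawn from the real means and library sizes. For CTVhigh against CTVlow PAX5-ELN, over 17878 simulated genes, 68% of genes changed 1.5-fold and 96% of genes changed 3-fold were recovered, and 8.38% of calls were false. For CTVlow PAX5-ELN against wild type, over 17881 genes, these were 78%, 100% and 8.72%. The changed genes, 100 at each fold, were drawn only from the better expressed genes. Simulated genes varied independently and had no trend over GC content. These shares therefore need not hold for scarce genes or for the real libraries.

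The alternatives tried were DESeq2 size factors, total library size alone, no immunoglobulin genes, no filter on low counts, a mean of at least 50 counts, DESeq2 (1.42.0), limma-voom, only the 4 libraries compared, robust dispersions, the replicate number as a block, each replicate left out in turn, an adjusted p under 0.01 for the overlap, and, for lists, an estimated correlation and fry. With an estimated correlation camera uses the 3 residual degrees of freedom, so fewer lists can pass. Counts divided by 2 and a correction of each library's trend over GC content and transcript length were added after seeing the data. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).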

Results

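Bulk RNA-seq was used to compare B cell progenitors of the mouse that carry a PAX5-ELN transgene with wild-type cells, and to compare transgenic cells that had kept a division-tracking dye with those that had diluted it. PAX5-ELN is a fusion of the B cell transcription factor PAX5 with the extracellular matrix protein elastin, found in B cell acute lymphoblastic leukaemia. CD19-selected bone marrow cells were stained with CellTrace Violet (CTV), a dye that is diluted at each division, and kept for 3 days in vitro on MS5 cells, a mouse bone marrow stromal line, with interleukin 7 (IL-7, 5 ng/ml), stem cell factor (10 ng/ml) and Flt3 ligand, listed as Flt3 (10 ng/ml). The labels call CTVhigh cells quiescent and CTVlow cells proliferating. The 6 libraries fell into 3 groups of 2: CTVhigh PAX5-ELN, CTVlow PAX5-ELN and CTVlow wild type. No CTVhigh wild-type library was analysed here, so the effect of the dye gate cannot be compared between genotypes. The labels do not say that replicates came from separate mice or cultures, and p-values then measure only the spread between these libraries, which may be technical.

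The libraries held 106147579 and 122164124 counts in CTVhigh PAX5-ELN, 150342332 and 166059066 in CTVlow PAX5-ELN, and 148883331 and 97865113 in wild type. Counts were seen for 20388 and 22778 genes in the CTVhigh libraries and for 23699 to 25255 genes in the other 4. Pearson correlations of log2 CPM (edgeR's counts scaled to the same library total) between replicates, taken across genes, were 0.971 in CTVhigh PAX5-ELN, 0.993 in CTVlow PAX5-ELN and 0.991 in wild type. Levels below are CPM after TMM scaling, as mean ± SD with n = 2, and fold changes with their standard errors come from an edgeR quasi-likelihood fit over 19000 genes.

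The genotype labels were looked at first. Pax5 (mm10 chromosome 4, 44524757 to 44710487) was at 996 ± 47.1 CPM in CTVlow PAX5-ELN, 981 ± 44.4 in CTVhigh PAX5-ELN and 834 ± 26.2 in wild type, a log2 difference of 0.26 ± 0.06 (SE) between the CTVlow groups (edgeR adjusted p = 0.0288). The Pax5 call was lost when CTVlow PAX5-ELN replicate 1 (adjusted p = 0.135), wild-type replicate 1 (0.124) or wild-type replicate 2 (0.249) was left out. Reads of Eln (chromosome 5, 134702593 to 134747323) were few, at 1.07 ± 0.183 CPM in CTVhigh PAX5-ELN, 0.318 ± 0.078 in CTVlow PAX5-ELN and 0.0137 ± 0.0194 in wild type, where 1 of the 2 libraries had none. The Eln difference between CTVhigh and CTVlow PAX5-ELN did not pass in the main fit. It passed under some alternatives, such as limma-voom (log2 fold change 1.73, adjusted p = 0.0137) and DESeq2 (1.75, 0.0112). The files do not tell whether transgene reads were counted to the mouse genes. Xist and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were all detected in each of the 6 libraries, with Xist between 187 and 383 CPM and Ddx3y between 18.1 and 32.2 CPM.

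The first comparison asked how CTVhigh PAX5-ELN cells differ from CTVlow PAX5-ELN cells. Several genes of B cell maturation and of MHC class II were lower in the CTVhigh libraries, while others of these groups were not. Cd74, the invariant chain of MHC class II (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), was at 7.0 ± 1.05 CPM in CTVhigh against 46.1 ± 1.16 in CTVlow, 6.60-fold lower (log2 fold change −2.72 ± 0.10 SE, edgeR adjusted p = 6.77e-06). Ltb, which encodes the cytokine lymphotoxin beta (chromosome 17, 35194439 to 35196320), was 14.7-fold lower, at 2.09 ± 0.203 against 30.6 ± 3.35 CPM. Ms4a1, which encodes CD20, was 8.29-fold lower, and the recombinase genes Rag1 and Rag2, which cut immunoglobulin loci, were 5.61-fold and 4.22-fold lower. Of the other class II genes, all but H2-Eb1 chosen here after their values were seen, H2-DMb2, H2-Eb1, H2-Aa and H2-DMa also fell (log2 fold changes −2.10, −2.03, −1.09 and −0.91), while H2-Ab1 and H2-DMb1 did not pass, with log2 differences of 0.29 ± 0.13 and 0.34 ± 0.24 (SE). The other genes among the 10 largest falls were Ephb2, Aqp1, Lrrc32, Mtcl1 and Plxdc1, between 4.45-fold and 6.10-fold.

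**Figure D1:**
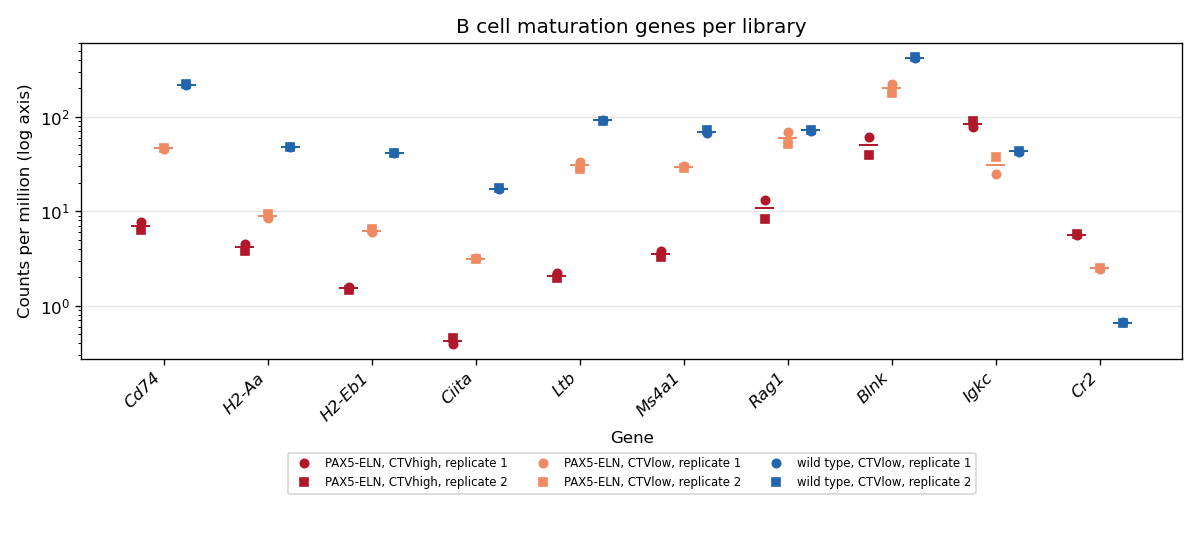
CPM (log axis) of 10 B cell genes in each of the 6 libraries, with a bar at each group mean. Cd74 falls from 218 CPM in wild type to 46.1 in CTVlow and 7.0 in CTVhigh PAX5-ELN, while Cr2 lies highest in CTVhigh PAX5-ELN at 5.65 CPM.

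Of 25 measured genes of small pre-B cells and later maturation, 12 fell and 5 rose (12 and 6 adjusted over the list alone), and the list was lower by camera (adjusted p = 1.41e-17), with an adjusted p of 0.118 with an estimated correlation between genes. Igkc, the kappa light chain constant gene, chosen here after its values were seen, was among those that rose (log2 fold change 1.44 ± 0.17 SE, edgeR adjusted p = 0.00151). Of 27 genes of B cell identity and PAX5 activation, 15 fell and 3 rose (15 and 3 adjusted over the list alone; camera adjusted p = 3.14e-07, and adjusted p = 0.118 with an estimated correlation). Blnk, the adaptor that links the pre-B cell receptor to its kinases, fell 4.01-fold, to 49.7 ± 15.4 CPM, and Cd79b, a receptor signalling chain, fell 1.47-fold. Cd19 fell 1.18-fold (adjusted p = 0.0194), a call lost without CTVlow PAX5-ELN replicate 1 (0.0846), wild-type replicate 1 (0.0540) or wild-type replicate 2 (0.0550), and with only the 4 libraries compared (0.0623). Of 21 pre-B cell receptor signalling genes, 8 fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.000833, adjusted p = 0.208 with an estimated correlation). Among them were the kinases Syk, 1.98-fold lower, and Lck, 1.68-fold lower. In the list of pro-B and large pre-B genes, 5 of 20 fell and 3 rose (5 and 4 adjusted over the list alone), and camera gave an adjusted p of 0.178, or 0.0275 without CTVhigh replicate 1. The median log2 fold change of that list was 0.01, its mean −0.18 and camera's direction down. The terminal transferase gene Dntt fell 2.49-fold, while Il2ra, the interleukin 2 receptor alpha chain found on pre-B cells, rose 2.90-fold, from 30.6 ± 8.24 to 88.9 ± 17.4 CPM. Kit, the receptor of stem cell factor, also passed as lower, a call lost without CTVlow PAX5-ELN replicate 1 (log2 fold change −0.37).

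Cell cycle genes did not separate the dye gates as a block. Mki67, a marker of cycling cells, was at 1526 ± 319 CPM in CTVhigh and 1593 ± 155 in CTVlow, a log2 difference of −0.06 ± 0.13 (SE) that did not pass the test (edgeR adjusted p = 0.786). Without CTVhigh replicate 1 the difference was −0.30 and Mki67 passed (adjusted p = 0.0456). Of 32 mitosis genes, 8 rose and 1 fell (12 and 2 adjusted over the list alone), with a median log2 fold change of 0.14. Ube2c and Aurka rose 1.31-fold and 1.23-fold, the call of Aurka being lost without CTVlow PAX5-ELN replicate 1 (adjusted p = 0.0892). The list was higher by camera (adjusted p = 0.00342). The list call was lost without CTVhigh replicate 1 (adjusted p = 0.267), and the list had an adjusted p of 0.633 with an estimated correlation. Of 33 DNA replication genes, 11 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of −0.05 (camera adjusted p = 0.00755, adjusted p = 0.249 with an estimated correlation). The largest of these falls was in Ccne2, a cyclin E that acts at entry into S phase, at 42.9 ± 0.889 against 80.1 ± 7.51 CPM (1.87-fold lower, edgeR adjusted p = 0.000499). Its relative Ccne1 fell 1.39-fold and Dhfr, which supplies folate for nucleotide synthesis, fell 1.40-fold.

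**Figure D2:**
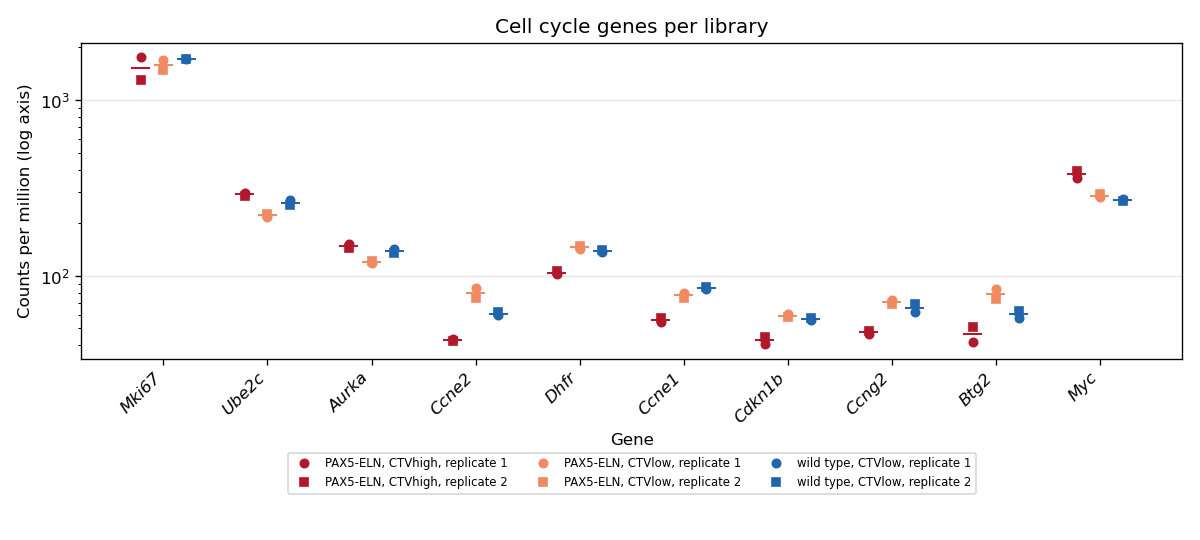
CPM (log axis) of 10 cell cycle genes in each of the 6 libraries, with a bar at each group mean. For Mki67 the CTVhigh libraries lie on either side of both CTVlow PAX5-ELN libraries, while Ccne2 and Dhfr lie lowest in CTVhigh PAX5-ELN, at 42.9 and 104 CPM.

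Of 28 genes of quiescence and cell cycle restraint, 9 fell and 3 rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.0826, adjusted p = 0.665 with an estimated correlation). With a median of −0.21, −0.19 and −0.11 the list passed without CTVhigh replicate 2 (camera adjusted p = 0.0148), without CTVlow PAX5-ELN replicate 1 (0.0213) and with the GC and length correction (0.0178). Those that fell included Cdkn1b, which encodes the cyclin-dependent kinase inhibitor p27 (42.8 ± 2.99 against 59.3 ± 1.62 CPM, 1.39-fold lower), Ccng2 (1.5-fold lower) and Btg2 (1.70-fold lower). Of 28 MYC and ribosome biogenesis genes, 11 rose and none fell (15 rose adjusted over the list alone; camera adjusted p = 2.03e-05, adjusted p = 0.305 with an estimated correlation). Myc itself rose 1.33-fold, from 285 ± 9.53 to 379 ± 23.9 CPM. Of 18 glycolysis genes, 4 rose (4 adjusted over the list alone; camera adjusted p = 0.00232, adjusted p = 0.596 with an estimated correlation), and without CTVhigh replicate 2 the list call was lost (camera adjusted p = 0.199). Hk2, a hexokinase, rose 1.28-fold, while the calls of Hk1, Pfkl and Pfkp were lost in 6, 7 and 2 of 18 alternatives, with edgeR adjusted p up to 0.106, 0.254 and 0.166.

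Among the genes with the largest rises in CTVhigh PAX5-ELN were 3 class I genes of the H2-Q region, H2-Q6 (chromosome 17, 35424850 to 35430055; 89.4 ± 16.3 against 3.10 ± 1.85 CPM), H2-Q5 and H2-Q7. These are close paralogs, and how the counting shared reads between them is not stated, so the level of each is uncertain. Prg3, which encodes an eosinophil granule protein, rose 15.9-fold to 20.1 ± 0.189 CPM, and Cox6a2, Megf6 and Htra3 rose 10.8-fold, 8.14-fold and 5.92-fold. The transcription factor genes Atf3 and Jdp2 rose 5.25-fold and 4.24-fold, and Rasd1 rose 4.41-fold. In the list of immediate early and handling stress genes, 6 of 20 rose and none fell (6 adjusted over the list alone; camera adjusted p = 8.39e-05, adjusted p = 0.345 with an estimated correlation), among them Nr4a1 at 2.51-fold. Of 12 measured myeloid markers 4 rose (4 adjusted over the list alone; camera adjusted p = 0.0018, adjusted p = 0.305 with an estimated correlation). All 4 were scarce in CTVhigh: Csf1r at 2.06 ± 0.0629 CPM, Mpeg1 at 2.98 ± 0.708, Siglech at 1.57 ± 0.798 and Cebpb at 1.18 ± 0.526. The Cebpb call was lost without CTVlow PAX5-ELN replicate 1 (edgeR adjusted p = 0.165) or 2 (0.1). Of 12 plasma cell markers 5 fell and 2 rose (5 and 4 adjusted over the list alone; camera adjusted p = 0.0488, adjusted p = 0.305 with an estimated correlation), led by Ighg2b, 8.31-fold lower. With DESeq2 size factors the plasma cell list missed the threshold (camera adjusted p = 0.0503), as it did without CTVlow PAX5-ELN replicate 2 (0.0934), with total library sizes (0.0531) and with only genes of a mean of at least 50 counts, where its median was 0.40 (0.390). The other lists gave camera adjusted p between 0.0654 and 0.943. Those were oxidative phosphorylation, genes repressed by PAX5, stem and multipotent progenitor, IL-7 and JAK-STAT, interferon, p53, NF-kB, adhesion and homing, T cell, NK, stromal, and erythroid and megakaryocyte genes. In the p53 list the median and mean were 0.05 and 0.06 while camera's direction was down. Of 24 stromal markers 1 fell and none rose (1 fell adjusted over the list alone), and without CTVhigh replicate 2 the stromal list was lower, with a median of −1.20 (camera adjusted p = 0.000527), and it passed without wild-type replicate 1 (0.0413) or 2 (0.0428). Other lists that gained a call, besides pro-B and quiescence above, were IL-7 and JAK-STAT without CTVhigh replicate 1 (0.00453) and with the replicate number as a block (0.0336), and oxidative phosphorylation without CTVlow PAX5-ELN replicate 2 (0.0286). Adhesion and homing gained one without CTVlow PAX5-ELN replicate 1 (0.0455), with the block (0.0371) and with the GC and length correction (0.0178).

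In total 2989 genes passed the threshold in this comparison, 1222 higher and 1767 lower in CTVhigh, and 339 and 432 of them differed by at least 2-fold. The count was 5109 without CTVhigh replicate 2, 1111 without CTVlow PAX5-ELN replicate 1, 1774 and 1760 without wild-type replicate 1 or 2, and 1634 when only the 4 PAX5-ELN libraries were fitted, and 781 genes were higher without CTVlow PAX5-ELN replicate 2. Fold changes rose with GC content across genes (Spearman rho 0.41 over 9775 genes, which are not independent replicates), and 2043 of the 2989 genes passed again after a correction for GC content and transcript length chosen after seeing the data.

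The second comparison asked how proliferating PAX5-ELN cells differ from proliferating wild-type cells. Several genes of MHC class II were among the largest falls in the transgenic cells, though no list of class II genes alone was fixed or tested. H2-Eb1 (chromosome 17, 34305867 to 34316674) was at 6.23 ± 0.258 CPM against 41.1 ± 0.0495 in wild type, 6.59-fold lower (log2 fold change −2.72 ± 0.09 SE, edgeR adjusted p = 4.30e-06). Ciita, the transactivator of these genes (chromosome 16, 10480059 to 10528418), was at 3.13 ± 0.0562 against 17.3 ± 0.352 CPM, 5.52-fold lower, and H2-Aa, Cd74 and H2-DMb2 were 5.43-fold, 4.74-fold and 4.66-fold lower. The other large falls were in Nrgn (7.90-fold), Mpp3 (4.32-fold), Mc1r (3.60-fold), Polm (3.48-fold) and n-R5-8s1, an annotated ribosomal RNA gene (12.0-fold). The Polm call was lost without CTVlow PAX5-ELN replicate 2 (adjusted p = 0.0570), wild-type replicate 1 (0.0536) or wild-type replicate 2 (0.0630).

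Of 27 B cell identity and PAX5-activated genes, 15 fell and 4 rose (15 and 4 adjusted over the list alone), with a median log2 fold change of −0.40 (camera adjusted p = 1.93e-09, adjusted p = 0.0651 with an estimated correlation). Cd72 and Cxcr5 fell 2.54-fold and 1.92-fold, Cd22, an inhibitory B cell coreceptor, fell 1.53-fold, and Cr2, a complement receptor of mature B cells, rose 3.76-fold from 0.660 ± 0.00785 to 2.49 ± 0.0772 CPM. Of 25 genes of small pre-B cells and later maturation, 11 fell and 5 rose (13 and 6 adjusted over the list alone; camera adjusted p = 2.58e-19, adjusted p = 0.0651 with an estimated correlation). Of 21 pre-B cell receptor signalling genes, 13 fell and none rose (14 fell adjusted over the list alone; camera adjusted p = 3.25e-10, adjusted p = 0.0651 with an estimated correlation). Cd79a fell 1.42-fold, Blk 1.55-fold, Cd19 1.36-fold and Lck 1.52-fold, and Ighm, the mu heavy chain gene, was 1.58-fold lower at 1708 ± 252 against 2691 ± 44.7 CPM.

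Of 18 genes repressed by PAX5, 5 rose and none fell (5 adjusted over the list alone; camera adjusted p = 9.84e-07, adjusted p = 0.0681 with an estimated correlation). Cd33, a myeloid surface receptor, was at 1.93 ± 0.401 CPM against 0.0482 ± 0.00943, Cd28 at 1.78 ± 0.0852 against 0.245 ± 0.0357, Ly6a, which encodes the stem cell antigen Sca-1, at 28.9 ± 1.56 against 11.8 ± 0.0873, and Grap2 at 73.3 ± 1.80 against 38 ± 1.85. In this comparison 3 of 12 myeloid and 17 of 24 stromal markers also rose and none fell, and Csf1r is in the myeloid list too. Whether RNA of other cells raised the genes repressed by PAX5 was not tested. Of 24 measured stem and multipotent progenitor genes, 5 rose and 1 fell (5 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.219). Its median log2 fold change was −0.04, its mean 0.07, and camera's direction was up. Kit, the receptor of stem cell factor, rose 1.78-fold (40.6 ± 3.08 against 22.8 ± 0.296 CPM), Mycn rose 1.88-fold and Flt3 was at 1.01 ± 0.276 against 1.56 ± 0.121 CPM (adjusted p = 0.183). Of 22 IL-7 and JAK-STAT genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0304, adjusted p = 0.522 with an estimated correlation), with Il2ra 4.65-fold, Socs3 1.82-fold and Il7r 1.39-fold higher. The Il7r call was lost without wild-type replicate 1 (edgeR adjusted p = 0.0686).

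Of 19 p53 and DNA damage response genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median log2 fold change of 0.63 (camera adjusted p = 3.49e-09, adjusted p = 0.389 with an estimated correlation). Zmat3 rose 3.53-fold, from 10.2 ± 0.216 to 36.2 ± 7.15 CPM, Pmaip1, which encodes the cell death protein NOXA, rose 2.13-fold, Ccng1 rose 1.93-fold and Trp53inp1 1.76-fold. Trp53 itself, chosen here after its values were seen, was the gene that fell (log2 fold change −0.28). In the quiescence and restraint list, where 4 of 28 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.341), Cdkn2a, which encodes the p16 and ARF tumour suppressors, rose 2.74-fold from 11.3 ± 1.02 to 30.8 ± 12.8 CPM. The Cdkn2a call was lost without wild-type replicate 1 (edgeR adjusted p = 0.0538).

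The largest rises in CTVlow PAX5-ELN were in Serpinh1, a collagen chaperone (36.3 ± 7.81 against 1.36 ± 0.391 CPM, 26.1-fold), Epas1 (12.8-fold), Hip1 (59.2 ± 2.58 against 5.82 ± 0.164 CPM, 10.2-fold), Sema6d (9.73-fold), Setbp1 (9.44-fold), Frmd4b (8.45-fold), Map6 (8.33-fold), Lpl (7.94-fold), Cxcl12 (7.71-fold) and Thbs2 (7.35-fold). Stromal markers, which MS5 feeder cells also express, moved with this contrast: 17 of 24 rose and none fell (19 rose adjusted over the list alone), with a median log2 fold change of 2.20 (camera adjusted p = 3.25e-10, adjusted p = 0.502 with an estimated correlation). Fn1 was at 67.0 ± 5.39 CPM in CTVlow PAX5-ELN against 15.0 ± 5.55 in wild type, Cxcl12, a stromal chemokine, at 36.9 ± 6.01 against 4.71 ± 2.51, and Bgn at 9.44 ± 0.469 against 2.16 ± 0.707. The Cxcl12 call was lost with robust dispersions (edgeR adjusted p = 0.0585). Of the other lists, oxidative phosphorylation (3 of 28 fell, 3 adjusted over the list alone; camera adjusted p = 0.00576), MYC and ribosome biogenesis (4 of 28 fell, 7 adjusted over the list alone; 0.0126), NF-kB (1 of 15 rose and 2 fell, 1 and 7 adjusted over the list alone; 0.0305), myeloid markers (3 of 12 rose, 3 adjusted over the list alone; 0.0304) and immediate early genes (1 of 20 fell, 1 adjusted over the list alone; 0.0304) passed. With an estimated correlation their adjusted p lay between 0.479 and 0.522. With only genes of a mean of at least 50 counts, the calls of the IL-7, NF-kB and immediate early lists were lost (camera adjusted p = 0.0590, 0.0718 and 0.0590), and with the GC and length correction that of the immediate early list (0.333). Leaving out 1 library ended the calls of oxidative phosphorylation, NF-kB and immediate early genes without CTVlow PAX5-ELN replicate 1 (0.0954, 0.0954 and 0.335), of NF-kB without wild-type replicate 2 (0.0649) and of MYC and ribosome biogenesis without wild-type replicate 1 (0.0544). The myeloid call was lost without CTVlow PAX5-ELN replicate 2 (0.185, median 0.21 against 0.68), wild-type replicate 1 (0.0588), or CTVhigh replicate 1 (0.0912) or 2 (0.0732), and with the replicate number as a block (0.0536). The remaining lists gave camera adjusted p between 0.0648 and 0.853, among them mitosis (2 of 32 rose and 5 fell, 2 and 6 adjusted over the list alone; 0.0790) and DNA replication (2 of 33 rose and 5 fell, 2 and 7 adjusted over the list alone; 0.0648). With the GC and length correction both passed with a negative median, mitosis at −0.11 (camera adjusted p = 0.00136; 4 fell and none rose) and DNA replication at −0.07 (0.0364; 1 fell and none rose), and mitosis also passed without wild-type replicate 2 (0.0344). NK markers passed without CTVlow PAX5-ELN replicate 1 (0.0307), CTVhigh replicate 1 (0.0421) or wild-type replicate 2 (0.0386) and with the GC and length correction (0.0447), and the quiescence list passed without CTVlow PAX5-ELN replicate 1 (0.0307). The others were glycolysis, pro-B and large pre-B, interferon, adhesion and homing, T cell, NK, erythroid and megakaryocyte, and plasma cell genes. For glycolysis and pro-B genes the medians of −0.07 and −0.10 and the means of 0.02 and 0.05 differed in sign, and camera's direction was down for both.

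**Figure D3:**
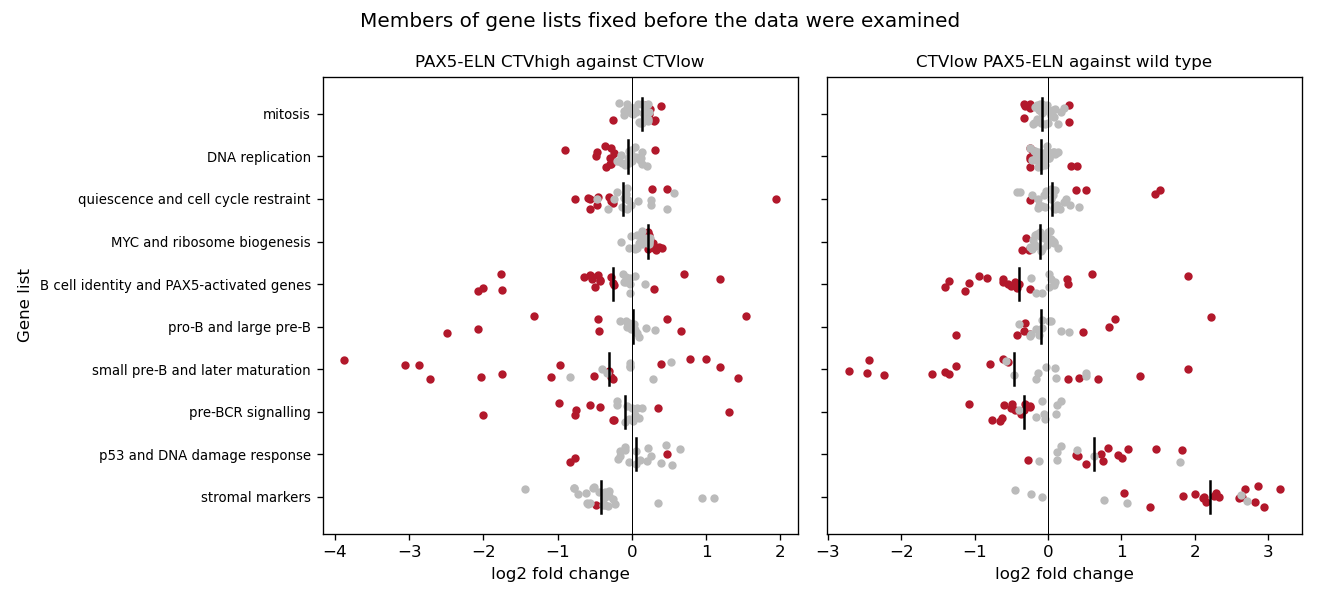
log2 fold change of each measured member of 10 gene lists in CTVhigh against CTVlow PAX5-ELN (left) and CTVlow PAX5-ELN against wild type (right). Red points passed an adjusted p of 0.05, grey points did not, and black bars are list medians: the stromal median is 2.20 on the right, and the maturation medians are −0.31 on the left and −0.47 on the right.

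In total 2888 genes passed in this comparison, 1845 higher and 1043 lower in CTVlow PAX5-ELN, and 544 and 118 of them differed by at least 2-fold. With total library size as the only scaling 2133 were higher and 750 lower. The count was 690 and 914 without wild-type replicate 2 or 1, 1622 and 1764 without CTVlow PAX5-ELN replicate 1 or 2, 4486 and 4498 without CTVhigh replicate 1 or 2, and 4527 when only the 4 CTVlow libraries were fitted. Fold changes fell with GC content across genes (Spearman rho −0.54), and 1550 of the 2888 genes passed again after the GC and length correction. For CTVhigh PAX5-ELN against wild type, given below, rho was −0.12, and 3995 of 4162 genes passed again. The trend was thus weakest where the CTVlow PAX5-ELN libraries were not compared, and it had opposite signs in the comparisons that share them.

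CTVhigh PAX5-ELN was also compared with CTVlow wild type, which mixes genotype with the dye gate. Ltb was 43.9-fold lower in CTVhigh PAX5-ELN, Ciita 40.4-fold, Cd74 31.2-fold, Ret 27.2-fold and H2-Eb1 26.9-fold. The largest rises were in Mir6240, Jhy, H2-Q6 and H2-Q7 and in Cd33, which was at 6.11 ± 0.459 CPM in CTVhigh PAX5-ELN against 0.0482 ± 0.00943 in wild type. The Mir6240 call was lost without wild-type replicate 1 (edgeR adjusted p = 0.0721) or 2 (0.0628), with robust dispersions (0.1) and with limma-voom (0.0985). B cell identity, maturation and pre-B cell receptor signalling genes were lower here as well, with 17 of 27, 14 of 25 and 15 of 21 members falling and 4, 7 and 1 rising. These lists share members. Adjusted over the list alone, 17, 17 and 16 fell and 5, 7 and 1 rose, and each of the 3 lists had an adjusted p of 0.0360 with an estimated correlation. Median and mean differed in sign for the quiescence list (−0.12 and 0.08, direction down) and the stem and progenitor list (0.12 and −0.07, direction up), neither of which passed (camera adjusted p = 0.471 and 0.364). Markers of other cell types moved in this comparison too: 14 of 24 stromal markers rose and 1 fell (18 and 1 adjusted over the list alone; median 1.81, camera adjusted p = 0.00074), and 6 of 12 myeloid markers rose (7 adjusted over the list alone; median 2.05, camera adjusted p = 0.00025). With an estimated correlation their adjusted p were 0.622 and 0.328. Genes repressed by PAX5 (9 rose, 3 fell, camera adjusted p = 3.64e-05) and p53 genes (10 rose, 2 fell, 4.51e-05) also passed. So did DNA replication (1 rose, 14 fell, 0.000624) and IL-7 genes (9 rose, 3 fell, 0.00454). NF-kB (2 rose, 8 fell) and glycolysis (4 rose) passed at 0.0479, but not with a mean of at least 50 counts (0.129 and 0.0876). With an estimated correlation none of these passed (0.0979 to 0.656). The remaining lists gave 0.160 to 0.471 by camera. The plasma cell list gained a call without CTVhigh replicate 1 (camera adjusted p = 0.0431). In all 4162 genes passed, 2180 higher and 1982 lower. The count was 6630 without CTVhigh replicate 2 and 2035 and 1905 without wild-type replicate 1 or 2.

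Genes that set CTVhigh PAX5-ELN apart from both CTVlow groups were counted next: 806 were higher and 950 lower against both, and 25 went in opposite directions. The libraries of CTVhigh enter both comparisons, so some overlap arises by chance. Simulated libraries without group effects gave a mean of 0.1 genes higher and 0.05 lower, but almost no gene is called in them, so these values set no expectation for lists of this length. Independent lists of these sizes would share 140 and 184. With 2 CTVhigh libraries they could not be split, and part of the excess may come from sharing them. The correlation of the fold changes across genes, which are not independent replicates, was 0.774 against 0.510 in the simulations, and their covariance 0.916 against 0.116. Lower against both were 14 of 27 B cell identity genes (Fisher's exact test, two-sided, adjusted p = 2.91e-10), 11 of 25 maturation genes (2.59e-07), 8 of 21 pre-B cell receptor genes (6.59e-05), 9 of 28 quiescence and restraint genes (6.59e-05) and 9 of 33 DNA replication genes (0.000235). Higher against both were 4 of 12 myeloid markers (0.00969), 5 of 25 maturation genes (0.0244), 4 of 18 genes repressed by PAX5 (0.0367) and 4 of 20 immediate early genes (0.0482). These tests treat genes as independent, which members of a list are not, and some genes are in several of these lists. The background was all 19000 tested genes, of which 8750 had a mean log2 CPM above 3. Lists were not matched to it for expression level, so part of the enrichment may come from that. By camera the quiescence list passed in neither comparison (adjusted p = 0.0826 and 0.471). DNA replication passed in both by camera (adjusted p = 0.00755 and 0.000624) and by fry (0.00184 and 0.000372). With an estimated correlation it passed in neither (0.249 and 0.111). The leading genes were H2-Q6, H2-Q5, Prg3, Cox6a2 and H2-Q7 among the higher, and Ltb, Klhl14, Ret, Ms4a1 and Ciita among the lower. Klhl14, at 0.343 ± 0.439 CPM in CTVhigh, lost its call against CTVlow PAX5-ELN without replicate 1 of that group (edgeR adjusted p = 0.105), with robust dispersions (0.0938), with only the 4 libraries compared (0.0704) and with DESeq2 (0.0832). The counts higher and lower were 1451 and 2015 without CTVhigh replicate 2, 278 and 490 without CTVlow PAX5-ELN replicate 1, 412 and 496 without wild-type replicate 1, and 398 and 493 without wild-type replicate 2.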

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

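Of the alternatives here, counts divided by 2 and the GC and length correction were chosen after seeing the data, and the others were fixed before. The counts of calls stayed within 1.5 times under DESeq2 size factors, total library size, no immunoglobulin genes, a mean of at least 50 counts, robust dispersions, limma-voom, halved counts and the GC and length correction. The correction gave 2604, 2037 and 4611 calls in the 3 comparisons, in the order of the report, of which 2043, 1550 and 3995 were shared with the reported calls. The lower genes of CTVlow PAX5-ELN against wild type numbered 1587 with no filter on low counts and 1582 with DESeq2. With only the 4 libraries compared, CTVhigh against CTVlow PAX5-ELN gave 1634 calls (610 higher, 1024 lower; 1623 shared), CTVlow PAX5-ELN against wild type 4527 (2804 higher, 1723 lower; 2884 shared), and 514 genes were higher and 571 lower against both. At an adjusted p under 0.01 in both comparisons, 282 were higher and 405 lower. Except for the stricter threshold, the cause was not tested.

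Leaving out 1 library at a time, with the lone library of a group assumed to vary like the others, gave 1111 to 5109 calls for CTVhigh against CTVlow PAX5-ELN (321 to 2067 higher, 790 to 3042 lower). For CTVlow PAX5-ELN against wild type it gave 690 to 4498 calls (513 to 2798 higher, 177 to 1858 lower), and for CTVhigh PAX5-ELN against wild type 1905 to 6630 (1019 to 3097 higher, 886 to 3533 lower). Against both groups 278 to 1451 were higher and 490 to 2015 lower. The lowest counts came without CTVlow PAX5-ELN replicate 1 for CTVhigh against CTVlow and for the genes changed against both groups, and without wild-type replicate 2 for the comparisons with wild type. List medians ran from 0.067 to 0.19 for mitosis and from −0.13 to −0.06 for DNA replication (CTVhigh against CTVlow), and from −0.41 to −0.37 for B cell identity and −0.10 to 0.07 for stem and progenitor genes (CTVlow PAX5-ELN against wild type).

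With an estimated correlation 30 of 72 list results lost their call, among them mitosis (median 0.14, adjusted p = 0.633) and DNA replication (−0.050, 0.249) in the first comparison and B cell identity (−0.40, 0.0651) in the second. That form of camera rests on the 3 residual degrees of freedom, so a lost call need not come from correlated genes. For B cell identity the estimated correlation was −0.021 in the first and −0.015 in the second comparison, below the preset 0.01. Its adjusted p still rose to 0.118 and 0.0651. By fry B cell identity passed in both (adjusted p = 0.00184 and 0.00153), and DNA replication in the first (0.00184). Fry tests a list against no change rather than against other genes: 12 list results that passed with camera did not pass with fry, such as mitosis (0.14, adjusted p = 0.145), and 11 passed only with fry, such as stem and progenitor genes in the second comparison (median −0.037, mean 0.065, direction up, 0.00216). A change of sign was counted only where a list had passed before or after it. The median of the plasma cell list in the first comparison became 0.40 with a mean of at least 50 counts (adjusted p = 0.390) and 0.022 with halved counts (0.0630), and that of the pro-B and large pre-B list became −0.0081 without CTVhigh replicate 1 (0.0275), with a range of −0.038 to 0.031 over the libraries left out in turn.

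Of the named genes that passed, 63 of 92, 52 of 96 and 84 of 100 in the 3 comparisons, in the order of the report, did so under every alternative run. Over all alternatives 5748 results for named genes stayed on their side of the threshold, 133 gained and 263 lost a call, and none changed sign while called. Ccne2 in CTVlow PAX5-ELN against wild type was among those lost, at an adjusted p of 0.765 after the GC and length correction.

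With the replicate number as a block the comparisons gave 3656, 3787 and 4681 calls, of which 2908, 2865 and 4037 were shared. The labels do not establish that equal numbers pair libraries, and the main fit did not pair them. Deviations of same-numbered libraries over 8750 expressed genes correlated at 0.39 between CTVhigh and CTVlow PAX5-ELN. They correlated at 0.05 between CTVhigh PAX5-ELN and wild type and at 0.18 between CTVlow PAX5-ELN and wild type, from 2 libraries per group.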

Other observations

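The GC and length tests below were set before their results were seen, and all other tests of explanations here were chosen only after the result was seen, and the bounds of the tests of swapped labels, cell cycle phases, mature B cells and Ciita were rewritten after it.

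Immunoglobulin heavy variable segments were counted at 12854 to 38812 counts per library. The leading segment was Ighv1-85 in CTVhigh PAX5-ELN replicate 1 (9.68% of these counts, 95% interval 9.19 to 10.2%) and in CTVlow PAX5-ELN replicates 1 and 2 (10.6% and 7.89%), and Ighv5-4 in CTVhigh PAX5-ELN replicate 2 (7.50%). In wild type it was Ighv14-2 (8.10% and 7.80%), while Ighv1-85 held 0.152% and 1.12%. Ighv14-2 held 0.686 to 2.02% in the PAX5-ELN libraries. Segments are similar in sequence, and how shared reads were counted is not given.

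Mitosis genes were not lower in the dye-retaining CTVhigh libraries than in CTVlow PAX5-ELN. In CTVhigh PAX5-ELN against wild type, 3 of 32 rose and 2 fell (median log2 fold change 0.06, camera adjusted p = 0.364). The MYC and ribosome biogenesis list did not pass there either (0.276). In CTVlow PAX5-ELN against wild type the medians were −0.09 for mitosis (camera adjusted p = 0.0790) and −0.11 for MYC (0.0126). For CTVhigh against CTVlow PAX5-ELN, a trend over GC content and length is argued against, since the mitosis median was 0.15 after its correction and 0.14 before. The bootstrap SE of 0.03 resampled genes, not libraries. It treats genes as independent, though their estimated correlation was 0.37, and does not cover the spread between libraries. Exchanged labels of the CTVhigh and CTVlow groups cannot be told apart. By members past the threshold, 3 of 4 lists ran the way an exchange would, but mitosis, 1 of them, is the pattern itself. Quiescence had 9 of 28 lower and 3 higher (camera adjusted p = 0.0826), and MYC and ribosome biogenesis 11 of 28 higher. Against an exchange, 11 of 33 DNA replication genes were lower and 1 higher in CTVhigh, the way the labels say. A different mix of cell cycle phases cannot be told apart either: replication genes lay below mitosis genes by 0.19 in list medians, and by 0.25 after the correction, but this difference itself prompted the test, and neither list passed with an estimated correlation (adjusted p = 0.249 and 0.633). Without CTVhigh replicate 1 the mitosis median was 0.067 and the list did not pass.

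Of 24 stromal markers, 17 rose in CTVlow PAX5-ELN against wild type, and 14 rose and 1 fell in CTVhigh PAX5-ELN against wild type (adjusted p = 0.502 and 0.622 with an estimated correlation). A GC and length trend is argued against for CTVlow PAX5-ELN against wild type, with a list median of 2.25 after correction and 2.20 before. The bootstrap SE of 0.20 resampled genes, whose estimated correlation was 0.67, and does not cover the spread between libraries. RNA carried over from MS5 feeder cells may be a source: of the 17 markers that rose, 100% were higher in wild-type replicate 1 than in replicate 2 and 88.2% were lower in CTVhigh replicate 1 than in replicate 2, against 50.4% and 54.7% of expressed genes. Among the abundant markers Fn1 was at 67.0 CPM and Cxcl12 at 36.9 CPM in CTVlow PAX5-ELN. Expression of these genes by the progenitors themselves was not tested.

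Of 25 genes of small pre-B and later maturation, MHC class II genes among them, 11 fell and 5 rose in CTVlow PAX5-ELN against wild type (adjusted p = 0.0651 with an estimated correlation), and 12 fell and 5 rose in CTVhigh against CTVlow PAX5-ELN (0.118). Fewer mature B cells in the mixture stay open for both steps. From CTVlow to CTVhigh, Igkc and Cr2 were higher (log2 fold changes 1.44 ± 0.17 and 1.18 ± 0.17 SE), while 12 genes of the list fell. Igkc was chosen after its value was seen, and a rise in it alone cannot count mature cells. From wild type to CTVlow PAX5-ELN, Igkc was at −0.47 ± 0.17 (SE, edgeR adjusted p = 0.0966) and Cr2 at 1.91. A GC and length trend is argued against by Cd74, at −2.05 in CTVlow PAX5-ELN against wild type and −2.84 in CTVhigh against CTVlow after correction. Lower Ciita may account for the step from wild type to CTVlow PAX5-ELN, where 7 of 7 class II genes under its control fell. In the step to CTVhigh, Ciita fell further (log2 fold change −2.87 ± 0.15 SE), but only 5 of 7 did. H2-Ab1 at 0.29 ± 0.13 and H2-DMb1 at 0.34 ± 0.24 (SE) showed no fall, but passed in neither direction (edgeR adjusted p = 0.180 and 0.371). Whether lower Ciita is the whole cause of that step therefore stays open. The effect of genotype and of dye gate stays open, with no CTVhigh wild type analysed here.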
